A study of Mus musculus with 40 samples.

How the data were processed

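The deposited scanner output of 40 Agilent 2-colour arrays was used, made with Feature Extraction 11.0.1.1 per the file headers. Per the file headers the signals are raw fluorescence intensity in both channels on a linear scale. Per the labels, 200 ng of total RNA from random lung sections with an RNA integrity number above 7 was labelled with Cy5, and universal mouse reference RNA with Cy3. The authors' value table gives log2 ratios of lung over reference, as the deposited values showed: their direction and scale were found by comparison, with a correlation across probes of 0.988 to 0.996 with the ratio computed here and medians of −0.0394 to −0.0111 per array. How the authors normalised that table is not stated further. Genes are not independent replicates, so this correlation describes 1 array at a time.

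Columns of mean signal are absent from the deposited files, so median signals and median local background were used. Background was corrected with normexp (offset 50), and log2 ratios were normalised within each array by loess. Spots of a probe were averaged. A gene was kept where its Cy5 signal was well above background on at least 4 of 5 arrays of at least 1 group, and its probe with the highest mean log2 intensity over all arrays stood for it. This left 23132 genes. Probe names were matched through transcript identifiers to RefSeq gene names of GRCm38.p6: of 55681 probes, 28026 matched 1 symbol, 27655 none and 0 several, which gave 21154 genes with a symbol before the filter. Of the 23132 genes kept and tested, 15208 had a symbol. The arrays' own annotation is on mm9, so no coordinates are printed, and features with no match kept their own name and were tested but not named.

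Groups followed the sample titles. In 6 arrays of slide 3 the dose in the characteristics differs from the title, and the title was used, since it gives 5 arrays per group. In 3 arrays the time differs: the title was followed in 2 of them and the characteristics in 1, for the same reason. In the 18 µg group of day 28, 2 arrays share a sample number and may come from 1 mouse. Both were kept, and their average was tried. Each array otherwise counts as 1 mouse.

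Differences were tested with limma 3.58.1 in R 4.3.3, with a mean for each of the 8 groups over all 40 arrays (32 residual degrees of freedom) and moderated, 2-sided tests. P values were adjusted by Benjamini-Hochberg over all genes of a comparison, and genes with an adjusted p under 0.05 are called. SE is the standard error of the log2 difference from this fit. The comparisons were each dose against the controls of its day, the difference between days of each of these effects, and 162 µg against 18 µg on each day. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 24 lists, and again with the correlation estimated from the data. Camera compares a list with all other genes. Files were read with the R packages jsonlite 2.0.0 and data.table (version 1.17.8), names and figures made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

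The 24 lists cover acute phase proteins, chemokines, cytokines, complement, interferon response, NRF2 targets, cholesterol biosynthesis, cell cycle, extracellular matrix, phagocyte lysosome genes, type 2 inflammation and the circadian clock. They also cover markers of neutrophils, alveolar macrophages, alveolar type 1 and 2 cells, club and mucous cells, ciliated cells, endothelium, B cells, T cells, cardiac muscle, adipocytes and red blood cells. Groups, comparisons, tests, filter, lists and alternatives were chosen before the data were examined. Genes were named by a rule of the same time. For 162 µg against control these are the 15 largest rises and 10 largest falls among called genes without overlap between groups, and for other comparisons the 5 largest of each, all with an official symbol. Up to 4 members of each list with the smallest p at 162 µg are added. Other list members are named as examples of those that passed over the list alone, chosen after their values were seen.

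Slides are a batch, each with 1 array of every group and scanned on its own day. Of 140 pairs of arrays that share a slide, 89 had a correlation of residuals above 0.1 (mean 0.181, range −0.711 to 0.813), against a mean of −0.0408 for pairs on different slides and of different groups. Slide as a block was therefore tried for every comparison. Further alternatives were Agilent's processed signals, median centring in place of loess, quantile scaling of mean intensity, Cy5 signals alone, the authors' value table, no filter, a filter on all arrays, the mean of a gene's probes, array weights, a fit of the compared arrays alone, the conflicting labels read the other way or left out, a fold threshold of 1.5, and leaving out each array. The mean log2 ratio of skeletal muscle markers as a covariate, Dbp minus Arntl as a covariate, and leaving out 10 arrays with muscle RNA were added after the data were seen. So were slide as a block for all exposed against all control arrays, and an estimated correlation in the fit with the muscle covariate. No array was left out of the main results. Sample numbers run in steps of 1 within each exposed group and in steps of 94 within each control group. Control numbers run from 3 to 379 on day 1 and from 50 to 426 on day 28. Those of exposed mice run from 100 to 118 and from 147 to 165. The labels do not say whether controls were collected together with exposed mice.

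The pipeline was tested on simulated data with 200 changed genes and shuffled residuals of the real arrays at 162 µg on day 1. It called 40 of 67 genes changed 1.5-fold, 61 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 15 false calls, and 0 calls in 6 unchanged comparisons. The residuals had group means removed and were shuffled once between arrays. The uneven spread of arrays with muscle RNA over the real groups was therefore not recreated. These counts do not show how many false calls that spread gives. With the preset correlation, camera called 10 lists that had not been shifted, and 0 when errors were independent. The calls with an estimated correlation are therefore given beside the preset ones.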

Results

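Lung RNA was measured in female C57BL/6 mice, an inbred laboratory strain, aged 5 to 7 weeks. Each mouse had received a single intratracheal instillation, a deposit of liquid into the windpipe, of titanium dioxide (TiO2) nanoparticles of 100 nm. The doses were 0, 18, 54 and 162 µg in 40 µl, and lungs were taken 24 h (day 1) or 28 days later. This gave 8 groups of 5 arrays, 40 in all. On each array the lung RNA carried the dye Cy5 and a universal mouse reference RNA, a pool made from cell lines, carried Cy3. A value is the log2 ratio of lung over reference RNA for 1 probe. The arrays lay on 5 slides, each with 1 array of every group. The Cy5 signal was well above its local background for 42.2 to 64.2% of probes per array, the median Cy5 intensity was 82 to 146, and no spot was saturated. The number of arrays limits the precision. The study's question, as its description gives it, is how lung gene expression depends on dose and on time after exposure.

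Markers of tissue other than lung were high in part of the arrays. The mean log2 ratio of 9 skeletal muscle markers, a list written after the data were seen, was at least 1.18 in 10 arrays and at most 0.02 in the other 30. Myl1, a myosin light chain of fast muscle, had a median log2 ratio of 6.51 in the 10 arrays and −0.80 in the others. The 10 arrays were 4 of 5 controls on day 1, 1 of 5 at 18 µg and 2 of 5 at 162 µg on day 1, and 1 of 5 at 18 µg and 2 of 5 at 162 µg on day 28. None was a 54 µg array or a day 28 control. Results are therefore also given with the muscle score as a covariate.

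**Figure D1:**
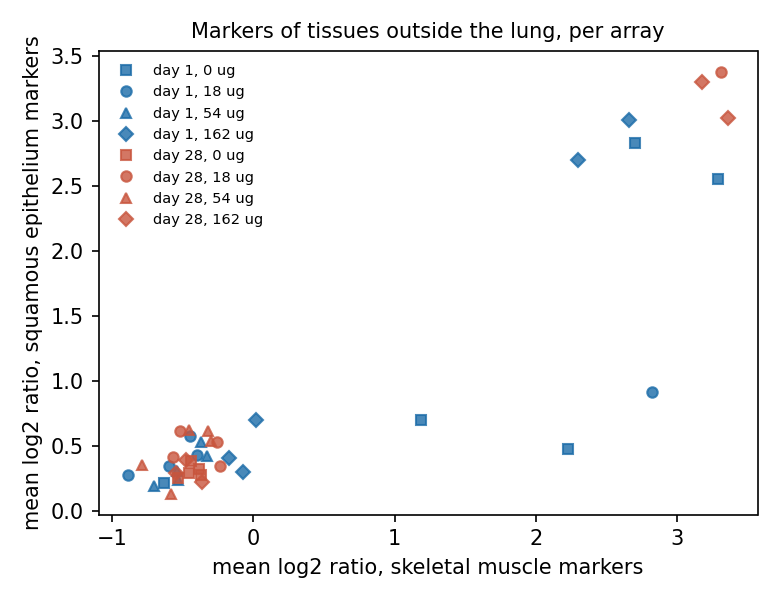
Mean log2 ratio (lung over reference RNA) of skeletal muscle markers on the x axis against that of squamous epithelium markers on the y axis, 1 point per array. The 10 arrays at or above 1.18 on the x axis lie apart from the other 30, which reach at most 0.02.

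The question of the first comparison was what the highest dose changed after 1 day. Genes for acute phase proteins, secreted early in inflammation, rose 1 day after 162 µg. Saa3, a serum amyloid A protein made in lung, rose 6.36-fold (log2 2.67, SE 0.49, n = 5 per group, adjusted p = 0.0109 in limma), from a mean log2 ratio of −2.16 ± 0.92 (SD) in controls to 0.51 ± 1.29. Saa1 rose 3.66-fold (log2 1.87, SE 0.29, adjusted p = 0.000772). Lcn2, an iron-binding protein of neutrophils and epithelium, rose 3.35-fold (log2 1.74, SE 0.22, adjusted p = 2.55e-05). Cxcl5, an epithelial chemokine that draws neutrophils, was called higher (log2 2.39, SE 0.44, adjusted p = 0.0109). It was well above background on 3 of 5 control arrays, and its log2 difference ran from 1.48 to 4.58 over the alternatives. Each of these genes was higher in the exposed array on 5 of 5 slides.

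Further genes rose at this dose and day. Ly6f, a membrane protein of the Ly6 family, rose 3.20-fold (log2 1.68, SE 0.18, adjusted p = 6.99e-07). Timp1, an inhibitor of matrix proteases, rose 2.99-fold (log2 1.58, SE 0.23, adjusted p = 0.000443). Hpx, which binds free heme, rose 2.52-fold and Ly6i 2.53-fold (adjusted p = 0.000455 and 0.0175). Noxo1, the organizer of an epithelial NADPH oxidase, rose 2.38-fold (SE 0.16 on the log2 scale, adjusted p = 2.55e-05). Saa2 was called higher (adjusted p = 0.0175), but its signal was well above background on 0 of 5 control arrays, so no fold is given. Smaller rises were those of Dhx37 (log2 0.83), Micall2 (0.74), B4galnt1 (0.73), Ear6 (0.64) and Slc17a9 (0.61). Over the alternatives the log2 difference of Ear6 ran from 0.37 to 1.58. The falls were small: Lsm8 by 0.78, Ube2b by 0.59 and Tpt1 by 0.26 on the log2 scale (adjusted p = 0.0399, 0.0436 and 0.0436).

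**Figure D2:**
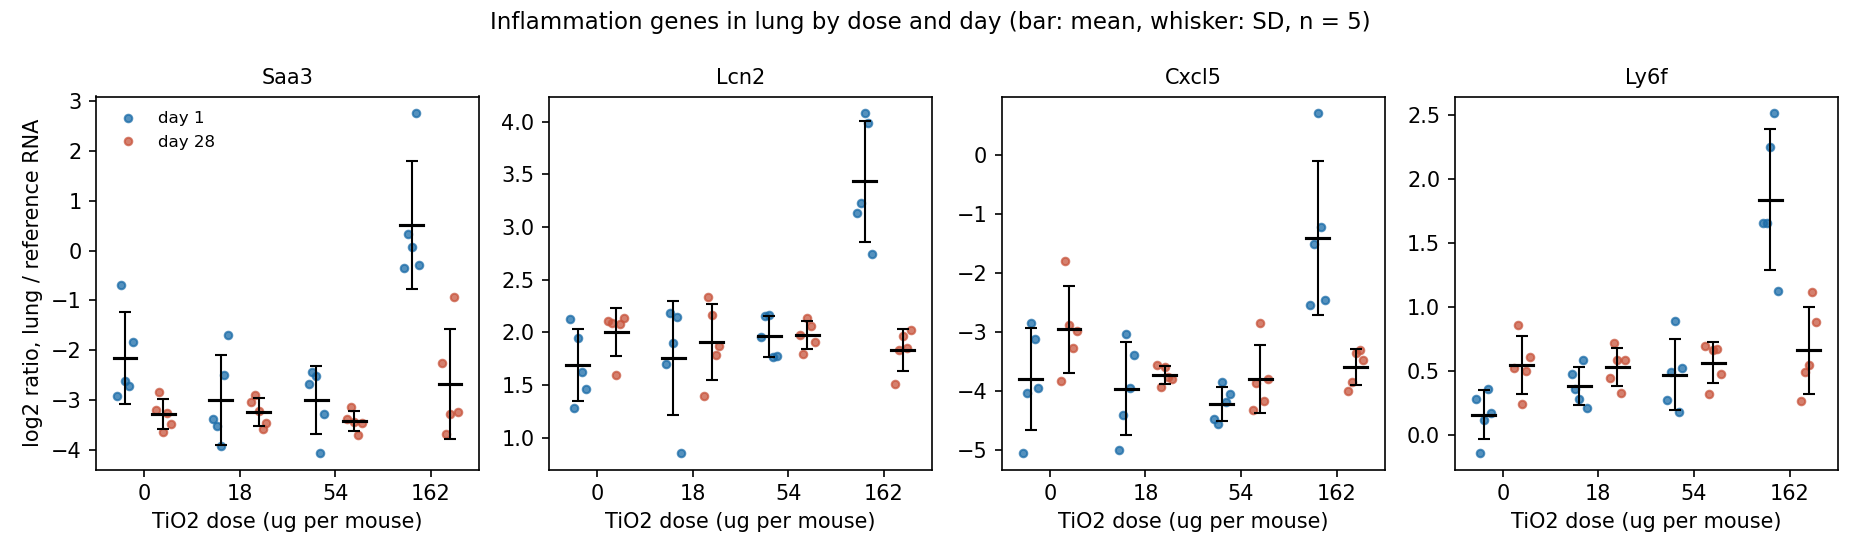
Log2 ratio (lung over reference RNA) of Saa3, Lcn2, Cxcl5 and Ly6f per array by dose (µg, x axis) and day, with a bar at the mean and whiskers of 1 SD over 5 arrays. Mean Saa3 was 0.51 at 162 µg on day 1 and −2.16 in the controls of that day, against −2.68 and −3.29 on day 28.

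By group, 13 of 14 measured acute phase genes were higher at 162 µg on day 1, of which 5 were called over all genes and 8 adjusted over the list alone (those above with Cd14, Itih4 and Cp). The list rose as a whole (adjusted p = 3.05e-15 in camera, 0.000734 with an estimated correlation). Its median member was higher on 5 of 5 slides, by log2 0.37 to 1.26. Of 20 chemokines, 19 were higher, 1 was called over all genes and 12 adjusted over the list alone, among them Ccl3, Ccl7, Cxcl1 and Ccl17 (median log2 0.64, adjusted p = 8.31e-09, 0.00161 with an estimated correlation, 4 of 5 slides). Cholesterol biosynthesis genes were higher in 17 of 19 (median log2 0.28, adjusted p = 0.000889), with 0 called over all genes and 1, Mvd, adjusted over the list alone. That list's call rests on the preset correlation (adjusted p = 0.485 with an estimated correlation). The other 21 lists were not called (adjusted p = 0.061 to 0.878). Neutrophil markers were higher in 10 of 14 (median log2 0.07, adjusted p = 0.567), alveolar macrophage markers were higher in 5 of 14 (median −0.09), and cardiac muscle and adipocyte markers had medians of 0.05 and 0.22. Single mediators that did not pass over all genes were Ccl17 at 1.22 (SE 0.31, adjusted p = 0.0827), Cxcl10 at 0.87, Il6 at 0.68 and Tnf at 0.18 on the log2 scale, of which Ccl17, Cxcl10 and Il6 passed adjusted over their list alone. With the muscle covariate cell cycle (0.0209) and club and mucous cell genes (0.0317) were called higher as well, but not with an estimated correlation in that fit (0.828 and 0.844).

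In total 29 of 23132 genes were called at 162 µg on day 1, 23 higher and 6 lower. Over all genes 280 had no overlap between the groups, 23 of the called ones among them, where chance gives 0.79% of genes. With slide as a block the count was 267 (143 higher), with the muscle covariate 687 (265 higher), and in both all 29 were among them. Without the 10 arrays with muscle 3 genes were called, with the day 1 controls reduced to 1 array, whose spread is then taken from the other groups. Leaving out 1 array gave 9 (without 162 µg replicate 3) to 251 (without 162 µg replicate 2). Cy5 signals alone gave 37 calls (23 higher). Median centring, which took the median of all genes from −0.007 to −0.106, gave 9 (8 higher). A fit of the compared arrays alone and the doses of the characteristics each gave 0, and array weights gave 13.

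At 54 µg on day 1, no member of the 24 lists was called over all genes, and 7 of the 14 called features had an official symbol. Arl4d, a small GTPase, rose 2.62-fold (log2 1.39, SE 0.27, n = 5 per group, adjusted p = 0.0262 in limma). Gatad2b, a subunit of a chromatin repressor complex, rose by 0.73 and Vps37b, part of the endosomal sorting machinery, by 0.70 on the log2 scale (adjusted p = 0.022 and 0.0169). Tnfrsf4, a costimulatory receptor of T cells, rose by 0.70 and Inpp5a, an inositol phosphatase, by 0.65 (adjusted p = 0.0467 and 0.022). All of these were higher on 5 of 5 slides. Saa3 stood at −0.84 (SE 0.49, adjusted p = 0.443) and mean Lcn2 was 1.96 ± 0.20 (SD) against 1.69 ± 0.34 in controls.

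Among the lists at 54 µg on day 1, 5 were called with the preset correlation and 0 with an estimated one. Cell cycle genes were lower in 14 of 18 (adjusted p = 0.000362, 0.671 with an estimated correlation), with 0 called over all genes and 3, Mki67, Birc5 and Top2a, adjusted over the list alone. T and NK cell markers were higher in 11 of 13 (adjusted p = 0.000796, 0.712 with an estimated correlation), with Cd3d, Cd8a and Lck adjusted over the list alone and 0 over all genes. All 12 cardiac muscle markers were lower (median log2 −1.25, adjusted p = 0.000796, 0.712 with an estimated correlation), as were all 9 adipocyte markers (median −1.35, adjusted p = 0.0237, 0.712 with an estimated correlation). Complement genes were lower in 12 of 15 (median −0.42, adjusted p = 0.00967, 0.712 with an estimated correlation). With the muscle covariate the adjusted p was 0.0172 for cell cycle, 0.37 for T and NK cell markers, 0.944 for cardiac muscle, 0.284 for adipocyte and 0.37 for complement genes. It also called interferon response genes lower (0.000112) and cholesterol biosynthesis genes higher (0.0172), which without it had 0.371 and 0.949. With an estimated correlation in the fit with the covariate 0 lists were called (0.801 for cell cycle, 0.601 for interferon and 0.801 for cholesterol genes). The other 19 lists had adjusted p = 0.067 to 0.949 without the covariate.

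Limma called 14 genes at 54 µg on day 1, 10 higher and 4 lower, and 931 of all genes had no overlap between the groups, 11 of the called ones among them (chance, 0.79% of genes). A fit with slide as a block gave 178 (124 higher, all 14 among them), while the muscle covariate gave 3 with 1 of the 14, and none of the 5 genes named above passed (adjusted p = 0.0528 to 0.105). Leaving out 1 array gave 0 (without 54 µg replicate 4) to 296 (without control replicate 1, the day 1 control without the muscle signal). Median centring gave 1 (1 higher), a fit of the compared arrays alone 1, array weights 2455 and Cy5 signals alone 11 (9 higher).

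At 18 µg on day 1, 0 genes were called in limma, with 1763 at an unadjusted p under 0.05. Of the clock genes, 9 of 12 passed adjusted over the list alone, 6 higher and 3 lower, against 0 over all genes. Per2, Per3, Dbp and Nr1d2 were among those 9. The clock list was called with the preset correlation (median log2 0.40, adjusted p = 0.0245, 0.322 with an estimated correlation). Cell cycle genes were lower in 14 of 18 (median −0.23, adjusted p = 0.00121, 0.613 with an estimated correlation) on 5 of 5 slides. Cardiac muscle markers were lower in 10 of 12 (median −0.97, adjusted p = 0.0245, 0.979 with an estimated correlation), and matrix genes were lower in 14 of 18 (adjusted p = 0.0485, 0.613 with an estimated correlation). Slide as a block moved these last lists to 0.0501 each, and the muscle covariate moved all 4 to between 0.0632 and 0.941. The other 20 lists had adjusted p = 0.0525 to 0.984. Without control replicate 1 limma called 25 genes, and without 18 µg replicate 2 it called 5.

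On day 28 the question was which genes differed from controls after that longer time. At 18 µg circadian clock genes, whose RNA rises and falls over the day, were among those called. Dbp, a clock output factor, rose 6.05-fold (log2 2.60, SE 0.34, n = 5 per group, adjusted p = 9.06e-05 in limma), from a mean log2 ratio of 0.22 ± 0.99 (SD) to 2.82 ± 0.38. Per1 rose 3.34-fold and Per2 2.94-fold (both adjusted p = 0.0094), and Usp2, a deubiquitinase under clock control, rose 3.61-fold (adjusted p = 0.0313). Arntl, the clock activator that peaks opposite to Dbp, fell 3.37-fold (log2 −1.75, SE 0.32, adjusted p = 0.00424). Map3k6, a stress kinase, rose 2.93-fold (adjusted p = 0.00162). Spon2, a secreted matrix and immune protein, fell 3.87-fold, and Rasl11a fell 2.75-fold (adjusted p = 0.000674 and 9.06e-05). Sox4, a transcription factor, fell 2.30-fold and Isg15, an interferon-induced ubiquitin-like protein, fell 2.29-fold (adjusted p = 0.00422 and 0.00127). All these directions held on 5 of 5 slides.

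**Figure D3:**
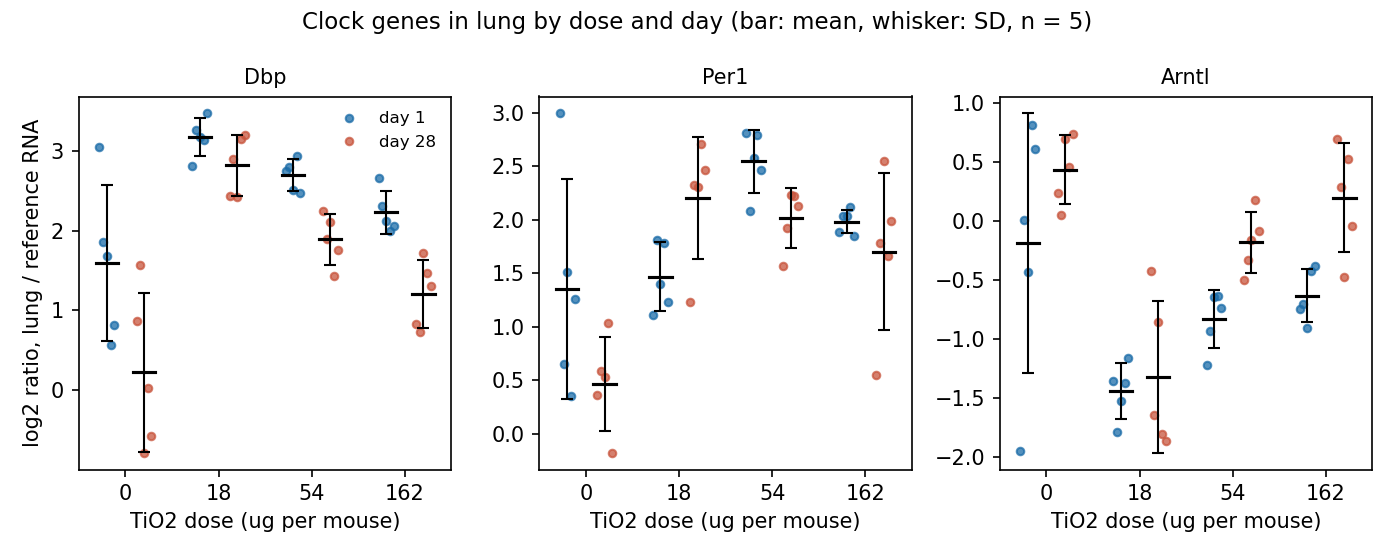
Log2 ratio (lung over reference RNA) of Dbp, Per1 and Arntl per array by dose (µg, x axis) and day, with a bar at the mean and whiskers of 1 SD over 5 arrays. On day 28 mean Dbp was 0.22 in controls and 2.82 at 18 µg, and mean Arntl was 0.43 and −1.32.

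The clock list rose at 18 µg on day 28 (adjusted p = 2.38e-08, 0.000237 with an estimated correlation). Of its 12 measured genes, 5 were called higher and 1 lower over all genes, and 9 higher and 2 lower adjusted over the list alone. All 18 cell cycle genes were lower (median log2 −0.36, adjusted p = 2.01e-09, 0.0661 with an estimated correlation), with 0 called over all genes and 10 adjusted over the list alone, Mki67 and Mcm2 among them. All 18 interferon response genes were lower too (median −0.29, adjusted p = 6.95e-06, 0.267 with an estimated correlation), with 1, Isg15, called over all genes and 3 adjusted over the list alone. Matrix genes were lower in 15 of 18 (adjusted p = 0.00743, 0.267 with an estimated correlation), with 0 called over all genes and 6 lower, among them Col1a1, Col3a1 and Eln, and 1 higher adjusted over the list alone. Alveolar type 2 genes (11 of 12 lower), endothelial markers (14 of 14 lower) and T and NK cell markers (13 of 13 lower) were called with the preset correlation (adjusted p = 0.00524, 0.00365 and 0.0047). With an estimated correlation these were 0.33, 0.579 and 0.579. The cardiac muscle and adipocyte lists moved the other way. Cardiac muscle markers were higher in 11 of 12 (median log2 1.53, adjusted p = 0.00461, 0.579 with an estimated correlation) and adipocyte markers in 9 of 9 (median 1.20, adjusted p = 0.0138, 0.673 with an estimated correlation). With the muscle covariate the adjusted p was 0.176 for adipocyte markers and 0.035 for B and plasma cell markers (lower, 0.0525 without it, 0.671 with an estimated correlation in that fit). Cell cycle genes had 0.0236 with the covariate and an estimated correlation. With median centring the median log2 was −0.02 for alveolar type 2, −0.03 for matrix, −0.09 for interferon, −0.12 for cell cycle and −0.15 for endothelial genes. The other 15 lists had adjusted p = 0.0525 to 0.99.

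In total 50 genes were called at 18 µg on day 28, 24 higher and 26 lower, and 1139 of all genes had no overlap between the groups, 44 of the called ones among them (chance, 0.79% of genes). The count was 339 (97 higher) with slide as a block and 121 (62 higher) with the muscle covariate, all 50 among them in both, and 155 without the 10 arrays with muscle, 48 of the 50 among them. Leaving out 1 array gave 22 (without control replicate 5) to 52. Median centring, which took the median of all genes from −0.005 to 0.124, gave 34 (30 higher), and array weights gave 676. Averaging the 2 arrays that share a sample number gave 29.

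At 54 µg on day 28 Isg15 fell 2.04-fold (log2 −1.03, SE 0.19, n = 5 per group, adjusted p = 0.0492 in limma), and the other probe of Isg15 gave −0.56. Vps37b rose by 0.61 and Tmem115, a Golgi protein, by 0.62 on the log2 scale (SE 0.12 each, both adjusted p = 0.0493). Ccdc71 rose by 0.64 (adjusted p = 0.0493), but its other probe gave 0.04. All 18 cell cycle genes were lower (median −0.28, adjusted p = 2.59e-07, 0.106 with an estimated correlation), with 0 called over all genes and 1, Birc5, adjusted over the list alone. All 7 red blood cell genes were lower (median −0.49, adjusted p = 2.74e-05, 0.106 with an estimated correlation), with 5 adjusted over the list alone, among them Hba-a1 and Hbb-b1, and 0 over all genes. Clock genes were higher in 9 of 12 (adjusted p = 0.00173, 0.0686 with an estimated correlation), with Nr1d1, Per1 and Dbp adjusted over the list alone and 0 over all genes. Alveolar type 2 genes were lower in 10 of 12 (adjusted p = 0.0214, 0.466 with an estimated correlation). Club and mucous cell genes were lower in 12 of 13 (adjusted p = 0.0489, 0.891 with an estimated correlation, 0.0655 with slide as a block, 0.068 with the muscle covariate). The other 19 lists had adjusted p = 0.0604 to 0.996.

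Limma called 7 genes at 54 µg on day 28, 3 higher and 4 lower, and 1110 of all genes had no overlap between the groups, the 7 among them (chance, 0.79% of genes). The blocked fit gave 71, the muscle covariate 93 and leaving out the 10 arrays with muscle 147, with the 7 among them each time, while leaving out 1 array of the pair of groups gave 0 (without control replicate 1, for example) to 6. Median centring took the median of all genes from 0.003 to 0.227 and gave 1388 calls (1356 higher). It turned the cell cycle median to 0.07 and the alveolar type 2 median to 0.08, and moved the red blood cell median to −0.08. Array weights gave 724 calls. No filter, the mean of a gene's probes, averaging the 2 arrays with a shared sample number, and reading the conflicting doses from the characteristics or leaving those arrays out each gave 0. Cy5 signals alone gave 9 calls (2 higher).

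At 162 µg on day 28, 0 genes were called in limma, with 1859 at an unadjusted p under 0.05. Of the genes that rose on day 1, Saa3 was at log2 0.61 (SE 0.49, adjusted p = 0.72), Cxcl5 at −0.64, Lcn2 at −0.16 and Ly6f at 0.11, each with n = 5 per group in limma. Isg15 stood at −0.79 (adjusted p = 0.609) and was lower on 5 of 5 slides.

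Of the lists at 162 µg on day 28, 8 were called with the preset correlation and 0 with an estimated one. All 12 alveolar type 2 genes were lower (median log2 −0.41, adjusted p = 0.000986, 0.308 with an estimated correlation), as were all 14 endothelial markers (median −0.32, adjusted p = 0.000986, 0.486 with an estimated correlation) and all 10 alveolar type 1 markers (median −0.43, adjusted p = 0.00388, 0.532 with an estimated correlation). Interferon response genes were lower in 15 of 18 (adjusted p = 0.00388, 0.486 with an estimated correlation), with Bst2 and Isg15 adjusted over the list alone and 0 over all genes. Cholesterol biosynthesis genes were higher in 15 of 19 (adjusted p = 0.00388, 0.486 with an estimated correlation), but within slides the median was higher on 2 of 5. Red blood cell genes were lower in 7 of 7 (adjusted p = 0.00399, 0.486 with an estimated correlation). Clock genes were higher in 9 of 12 (adjusted p = 0.0195, 0.308 with an estimated correlation), with Per1 and Dbp adjusted over the list alone and 0 over all genes. Club and mucous cell genes were lower in 12 of 13 (adjusted p = 0.0493, 0.662 with an estimated correlation, 0.0523 with slide as a block). With the muscle covariate the adjusted p was 0.506 for alveolar type 1, 0.12 for interferon and 0.157 for cholesterol genes. It called 7 further lists lower: cell cycle (6.14e-05), adipocyte (0.000824), complement (0.00521), matrix (0.00859), chemokines (0.00915), ciliated cell (0.00915) and cardiac muscle genes (0.0337). With an estimated correlation in that fit these 7 had 0.292 to 0.572, and the clock list alone was called (0.0183). Median centring moved the medians of alveolar type 2, type 1 and endothelial genes to −0.17, −0.18 and −0.14. The other 16 lists, acute phase (0.456) and chemokines (0.209) included, had adjusted p = 0.0509 to 0.885 without it. Slide as a block gave 1 called gene, and the muscle covariate and leaving out the arrays with muscle gave 2 each.

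Whether an effect differed between the days was tested as the effect on day 28 minus that on day 1. At 162 µg, 4 of the 5 called genes had a lower effect on day 28. Lcn2 was lower by log2 1.91 (SE 0.31, adjusted p = 0.0056), Timp1 by 1.80 (SE 0.33, adjusted p = 0.0232), Ly6f by 1.56 (SE 0.25, adjusted p = 0.0056) and Noxo1 by 1.25 (SE 0.23, adjusted p = 0.0232), with n = 5 in each of the 4 groups in limma. Frat2 was higher by 0.78 (SE 0.15, adjusted p = 0.0263), but its other probe gave 0.03. Each held on 5 of 5 slides. With the muscle covariate Lcn2 and Ly6f passed (adjusted p = 0.033 and 0.0226), and Timp1, Noxo1 and Frat2 did not (0.0587, 0.099 and 0.099). Acute phase genes had a lower effect in 13 of 14 (median log2 −1.18, adjusted p = 1.96e-15, 0.000671 with an estimated correlation), 1 over all genes and 9 adjusted over the list alone. Chemokines had a lower effect in 18 of 20 (median −0.67, adjusted p = 7.65e-10, 0.000765 with an estimated correlation), 0 over all genes and 6 adjusted over the list alone. Cytokine and inflammasome genes and neutrophil markers were not called (adjusted p = 0.401 each). A further 7 lists were called with the preset correlation alone, interferon (adjusted p = 0.000145, 0.355 with an estimated correlation) and club and mucous cell genes (0.000264, 0.355) first among them. The call of interferon ended with the muscle covariate (0.183).

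The 5 genes at 162 µg were all that limma called, 1 higher and 4 lower. Blocking on slide gave 10 with all 5 among them, the muscle covariate 2, and leaving out 1 array 2 (without day 28 control replicate 1) to 10 (without 162 µg day 1 replicate 5). Median centring, a fit of the compared arrays alone, the doses of the characteristics, leaving out the arrays with conflicting doses, and taking the conflicting times all from titles or all from characteristics each gave 0. At 18 µg and 54 µg limma called 0 genes between days, with 899 and 223 at an unadjusted p under 0.05. Slide as a block gave 1 and 0, and the muscle covariate 5 and 0. With the preset correlation 10 lists were called at 18 µg and 7 at 54 µg, and with an estimated correlation 0 at both. The lists with the largest medians were tissue markers, adipocyte genes at 2.31 (18 µg, adjusted p = 0.00018, 0.369 with an estimated correlation) and 1.39 (54 µg, adjusted p = 0.000993, 0.776 with an estimated correlation), and cardiac genes at 2.47 (18 µg, adjusted p = 4.22e-06, 0.272 with an estimated correlation). The muscle covariate ended these calls (0.983 and 0.112 at 18 µg for adipocyte and cardiac genes, 0.465 at 54 µg for adipocyte genes, whose direction it turned to lower). Cell cycle genes were lower at 18 µg (median −0.12, adjusted p = 0.0238, 0.537 with an estimated correlation) and at 162 µg (median −0.09, adjusted p = 0.0022, 0.355 with an estimated correlation). Median centring turned these medians to 0.14 and 0.23. The median of all genes was 0.128, 0.147 and 0.194 with it at 18, 54 and 162 µg, against −0.015, −0.018 and −0.012.

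The highest dose was also set against the lowest, a comparison that shares no control arrays with those above. On day 1 Saa3 was 11.4-fold higher at 162 µg than at 18 µg (log2 3.51, SE 0.49, n = 5 per group, adjusted p = 0.000183 in limma). Cxcl5 was called higher (adjusted p = 0.00373), but it was well above background on 1 of 5 arrays at 18 µg, so no fold is given, and its log2 difference ran from 0.89 to 5.24 over the alternatives. Slc26a4, an anion exchanger induced in airway inflammation, was higher by 2.21 (SE 0.42, adjusted p = 0.0155). Saa1 was higher by 1.98 and Lcn2 by 1.68 (adjusted p = 0.000257 and 6.77e-05). Acute phase genes were higher in 14 of 14 (median log2 1.03, adjusted p = 1.85e-24, 1.62e-05 with an estimated correlation), 5 over all genes and 9 adjusted over the list alone. All 18 cell cycle genes were higher (median 0.31, adjusted p = 9.37e-13, 0.0136 with an estimated correlation), 0 over all genes and 2, Mcm2 and Mcm5, adjusted over the list alone. Chemokines were higher in 17 of 20 (adjusted p = 5.62e-09, 0.00161 with an estimated correlation), 1 over all genes and 3 adjusted over the list alone. Cholesterol biosynthesis genes were higher in 19 of 19 (median 0.31, adjusted p = 6.15e-09, 0.0516 with an estimated correlation) and neutrophil markers in 12 of 14 (median 0.28, adjusted p = 0.00474, 0.217 with an estimated correlation). Cardiac muscle markers were higher too in 10 of 12 (median 1.28), as were adipocyte markers in 9 of 9 (median 1.14). Both had adjusted p = 0.00874, 0.485 with an estimated correlation, and 0.2 and 0.253 with the muscle covariate. Without the arrays with muscle RNA both were still called higher (0.00198 and 0.00244). A further 7 lists were called with the preset correlation alone. Among these, median centring turned the median of interferon genes from 0.12 to −0.01 and that of matrix genes from 0.10 to −0.02.

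All 11 genes called between 162 µg and 18 µg on day 1 were higher at 162 µg, and 120 of all genes had no overlap between the groups, 10 of the called ones among them (chance, 0.79% of genes). With slide blocked the count was 18 with the 11 among them, the muscle covariate gave 16, and leaving out 1 array 9 (without 162 µg replicate 4) to 23 (without 18 µg replicate 5). A fit of the compared arrays alone and the doses of the characteristics each gave 0. On day 28 limma called 0 genes, with 986 at an unadjusted p under 0.05, and 17 without 18 µg replicate 1. Clock genes were lower at 162 µg in 9 of 12 (median −0.45, adjusted p = 1.37e-06, 0.00181 with an estimated correlation), 0 over all genes and 7 lower and 1 higher adjusted over the list alone. Of 12 lists called on day 28 this was the single call with an estimated correlation. Cell cycle genes were higher in 16 of 18 (median 0.28, adjusted p = 4.04e-09, 0.0748 with an estimated correlation), B and plasma cell markers higher in 11 of 11 (median 0.41, adjusted p = 1.37e-06, 0.328 with an estimated correlation) and ciliated cell markers lower in 12 of 12 (median −0.39, adjusted p = 1.37e-06, 0.328 with an estimated correlation). Cardiac and adipocyte markers were lower (medians −0.68 and −0.92, adjusted p = 0.013 and 0.015, both 0.574 with an estimated correlation).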

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

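All tests of explanations and the counts over other splits of the arrays were chosen after the results were seen, while the test for a single distant array and the test of differences between days were planned.

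The first pattern is skeletal muscle RNA in 10 arrays of 5 groups, with scores of at least 1.18 against at most 0.02, and the first component of the residuals held 42.3% of their variance. Poor hybridization is argued against, since 1 of the 10 arrays lay outside the other 30 in the percent of Cy5 probes above background. Tissue from outside the lung, such as muscle, fat or squamous lining taken with the lung sections, may be the source. Over all arrays, with group means removed, the adipocyte list ran against the alveolar and endothelial lists (r = −0.589, permutation p = 6e-05, adjusted 0.00012 over 2 relations, rho −0.489 with permutation p = 0.0012, r = −0.484 without the 2 farthest arrays, and −0.808 to −0.215 within slides). This relation concerns fat and does not hold the muscle score. It therefore cannot decide on the source of the muscle RNA in the 10 arrays. The other relation, adipocyte list with percent of probes above background, had r = 0.322 (permutation p = 0.043, rho 0.263, permutation p = 0.1). In 7 of the 10 arrays the squamous score was at least 2.56 too, against at most 0.92 in all other arrays, the remaining 3 included, and whether exposure plays a part cannot be told apart, since 6 of 30 exposed and 4 of 10 control arrays were above the gap (Fisher's exact p = 0.232).

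The second pattern is that control arrays lay apart from exposed arrays when all doses and both days were pooled, with 1257 genes called (399 higher in exposed arrays), clock genes included, against 0 on day 1 alone and 271 on day 28 alone. For the clock genes, Dbp minus Arntl differed between 162 and 18 µg by log2 −3.126 on day 28 and −1.75 on day 1. It was lower at 162 µg on 5 of 5 slides on both days (exact permutation p = 0.00794 each, n = 5 arrays per group). At 18 µg on day 28, 2 of these arrays share a sample number. Sample numbers of exposed mice rise with dose on each day, from 100 to 118 and from 147 to 165. Sample order and dose therefore cannot be told apart. The difference cannot decide on an exposure effect that grows with dose. A different clock time at sampling cannot be told apart from exposure for the clock genes: 10 of the 10 other clock genes moved with their phase at 18 µg on day 28, but that comparison is the one that showed the pattern, and the labels give no sampling hour. With the clock index as a covariate 472 genes were called, 435 of them among the 1257. That index is a single linear term, Dbp minus Arntl, and may not hold all of clock phase. Clock phase as the whole cause therefore stays open. With the muscle score as a covariate 2326 genes were called, all 1257 among them. This argues against skeletal muscle RNA, as that score measures it, as the whole cause. The score is a single linear term too and holds no fat or squamous markers, so RNA of other tissue stays open. In 100 choices of 5 arrays a day as controls only the real one gave as many, with 1257 against at most 693. Chance is less likely by this but is not excluded, since the other choices were not balanced over slides. With slide as a block the real one gave 2099, all 1257 among them, against at most 341. The other choices did not keep 1 control a day on each slide as the real one does, so the blocked counts decide nothing. An effect of exposure common to all doses stays open, as does any difference in handling that sets controls apart. Control sample numbers run in steps of 94 and those of exposed mice in steps of 1. A difference in handling would enter every comparison of a dose with controls.

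The third pattern is the dose of 6 arrays on slide 3, which differs between title and characteristics. If the characteristics were right, the array they place at 162 µg on day 1 should have the acute phase level of that dose, but it had 0.897 against 1.945 for the array titled 162 µg, a difference of −1.048. The other 162 µg arrays of that day had 1.73 to 2.69 and the other 18 and 54 µg arrays 0.62 to 1.29. This argues against the characteristics for that pair of arrays, and says nothing of the day 28 arrays.

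Other splits of the arrays were counted for each comparison, 100 each, the real one included, with the fit without slide unless the block is named. For 54 µg on day 1, 2 splits gave as many (14 genes, highest other 16). On day 28 it was 1 split each for 18 µg (50 genes, highest other 9) and 54 µg (7 genes, highest other 0). Chance is less likely for these counts but is not excluded. The ranks were not adjusted over the comparisons, and the splits were not balanced over slides. In the 18 µg group of day 28, 2 arrays share a sample number and may come from 1 mouse. For the difference between days at 162 µg 3 splits gave as many as 5 genes, and the highest other was 1102. These splits mixed the arrays of both doses and both days freely. They cannot exclude chance for a difference between days. Without the block chance cannot be excluded for 162 µg on day 1, where 6 splits gave as many as 29, the highest 670. With slide as a block 2 splits gave as many as 267, the highest other 482. The splits did not keep 1 array of each group on each slide, as the real groups do. Counts with the block therefore cannot exclude chance. For 162 against 18 µg on day 1 it cannot be excluded without the block (22 splits, 11 genes, highest other 3686) or with it (15 splits, 18 genes, highest other 3110). With the block 3 splits gave as many for 54 µg on day 1 (178 genes, highest other 541). For 18 µg and 54 µg on day 28 these were 1 and 2 splits (339 and 71 genes, highest others 29 and 95). For the difference between days at 162 µg they were 4 (10 genes, highest other 3208). Chance cannot be excluded for the list counts at 162 µg on day 1 (84 splits, 3 lists, highest other 12) and day 28 (33 splits, 8 lists, highest other 15). Where 0 genes were called all 100 splits gave as many, with highest others of 822 for 18 µg on day 1, 0 for 162 µg on day 28, 1346 and 3 for the difference between days at 18 and 54 µg, and 789 for 162 against 18 µg on day 28. Splits with several times the real count point to a structure of the arrays, and the arrays with muscle RNA were looked at as such. Splits with more calls than the real one parted these arrays more unevenly for 18 µg on day 1 (a mean difference of 2.45 arrays between the sides, against 1.30 in other splits), for 162 µg on day 1 (1.60 against 1.02), for 162 against 18 µg on day 28 (3 against 1.19), and for the difference between days at 18, 54 and 162 µg (3.20 against 1.45, 4 against 1.35 and 4 against 1.79). For 54 µg on day 1 the single split with more calls placed 4 of these arrays on a side and 0 on the other, as the real split does. Muscle RNA therefore stays open there as the source of the calls. For the difference between days at 162 µg the real split placed 6 on a side and 2 on the other, so muscle RNA stays open there too. No such unevenness was seen for 162 against 18 µg on day 1 (1.19 against 1.28), so what lies behind those splits is open.

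In some groups of 5 a single array lay far from the others, by a gap that chance gives in about 1 in 20 groups, and 21 of 274 tests of a group did so. On day 1, control replicate 2 had a mean log2 ratio of chemokines of 0.361 (others −0.39 to −0.19) and a Tpt1 value of 1.053 (0.83 to 0.89), and control replicate 1 an Arl4d value of 4.058 (2.66 to 2.92). At 18 µg, replicate 4 had a cell cycle mean of −3.212 (−2.93 to −2.85) and replicate 5 an alveolar type 1 mean of 2.624 (3.95 to 4.15). At 54 µg, replicate 1 had an alveolar macrophage mean of 4.216 (3.74 to 3.81) and replicate 4 an Arl4d value of 5.009 (4.199 to 4.336). At 162 µg, replicate 4 was high in acute phase genes, 2.688 (1.73 to 1.94), and Saa3, 2.758 (−0.34 to 0.34). Replicate 3 of that group had a cardiac muscle mean of 1.976 (4.16 to 4.43) and replicate 2 a Slc17a9 value of −0.021 (0.28 to 0.39).

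On day 28, control replicate 4 was low in club and mucous cell genes, 2.218 (4.16 to 4.47), and cardiac muscle genes, 0.983 (3.00 to 3.71). At 18 µg, replicate 1 had an NRF2 target mean of 0.289 (−0.57 to −0.38), an alveolar type 1 mean of 2.849 (3.86 to 4.07) and a Per1 value of 1.231 (2.30 to 2.71). At 54 µg, replicate 5 had 62% of Cy5 probes above background (52.9 to 55.1%) and a complement mean of 2.109 (2.38 to 2.47). At 162 µg, replicate 4 had means of 1.487 for acute phase genes (0.59 to 0.80), 0.335 for chemokines (−0.47 to −0.24) and 1.196 for B and plasma cell markers (0.25 to 0.50). Of the arrays in these paragraphs, day 1 control replicate 2, 18 µg day 1 replicate 5, 162 µg day 1 replicate 4, 18 µg day 28 replicate 1 and 162 µg day 28 replicate 4 are among the 10 with muscle RNA.

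The effect of 162 µg was called different between the days, by the test of that difference, for Lcn2 (−1.909), Timp1 (−1.802), Ly6f (−1.563), Noxo1 (−1.245) and Frat2 (0.779), all on the log2 scale as day 28 minus day 1. In that order the calls were kept in 33, 24, 32, 26 and 18 of 40 alternatives. With the muscle covariate 2 of these genes, Lcn2 and Ly6f, were still called. Chance and muscle RNA stay open for this comparison, as said above.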

How the results depend on the processing

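The covariates and the removal of arrays with muscle RNA were tests chosen after the results were seen, the other alternatives were planned, and the cause of a change was not tested except where stated. Called genes are counted as in the report, and 125 changes of named genes, 48 of them called, were recomputed as well. The called ones had 1486 alternative values, of which 1040 had the direction and the call, 445 the direction alone and 1 the opposite direction. The others had 2306, of which 2275 were again not called in the same direction, 21 were called and 10 had the opposite direction. A fold threshold of 1.5 and leaving out the array with a day 1 title moved no count by more than 1.5 times. Quantile scaling of mean intensity leaves the log2 ratios as they were, so it could move no count. Its values among the alternative values above repeat the main ones. The counts that did move follow, each as genes called unless lists are named.

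With slide as the replicate block, which fits a level for each slide and so takes slide differences out of the error, 178 genes were called for 54 µg on day 1, 267 for 162 µg on day 1, 339 for 18 µg on day 28, 71 for 54 µg on day 28 and 1 for 162 µg on day 28. The block also gave 1 for the difference between days at 18 µg, 10 at 162 µg, and 18 for 162 against 18 µg on day 1. Array weights gave 79 for 18 µg, 2455 for 54 µg and 13 for 162 µg on day 1, 676, 724 and 3 on day 28, 7 for the difference between days at 18 µg, and 21 and 22 for 162 against 18 µg on days 1 and 28. A fit of the compared arrays alone, with fewer samples behind the error, gave 1 for 54 µg and 0 for 162 µg on day 1, 66 for 54 µg on day 28, 0 for the difference between days at 162 µg and 0 for 162 against 18 µg on day 1.

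Agilent's processed signals gave 3 for 54 µg on day 1, 2 for 54 µg on day 28 and 1 for 162 against 18 µg on day 28. Median centring gave 1 for 54 µg and 9 for 162 µg on day 1, 1388 for 54 µg on day 28 and 0 for the difference between days at 162 µg. Cd63 and Lamp1 at 162 µg on day 28 went from −0.31 and −0.23 to 0.019 and 0.103 with it. Cy5 alone gave 31 for 18 µg on day 28, 1 for the difference between days at 18 µg, and 8 lists for 162 µg on day 1. The authors' value table gave 1 for 54 µg on day 28 and 2 for 162 against 18 µg on day 28. Without the filter 0 genes were called for 54 µg on day 28 and 5 lists for 162 µg on day 1. The filter on all arrays gave 2 and the mean of a gene's probes 0 for 54 µg on day 28.

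Reading the dose of 6 arrays from the characteristics gave 7 for 54 µg and 0 for 162 µg on day 1, 26 for 18 µg and 0 for 54 µg on day 28, 0 for the difference between days at 162 µg, 0 for 162 against 18 µg on day 1, and 6 lists for 162 µg on day 1. Leaving these arrays out gave 5 for 54 µg and 10 for 162 µg on day 1, 0 for 54 µg on day 28, 0 for the difference between days at 162 µg, and 7 lists for 162 µg on day 1. Times from the characteristics gave 9 for 162 µg on day 1, 0 for its difference between days and 3 for 162 against 18 µg on day 1. Times from the titles gave 4, 0 and 2 for these, and 2 for 54 µg on day 28. Averaging the arrays with a shared sample number gave 29 for 18 µg and 0 for 54 µg on day 28.

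The muscle covariate gave 3 for 54 µg and 687 for 162 µg on day 1, 121, 93 and 2 for 18, 54 and 162 µg on day 28, 5 and 2 for the difference between days at 18 and 162 µg, and 5 lists for 162 µg on day 1. Without the 10 arrays with muscle RNA, which leaves 1 day 1 control, the counts were 5, 2 and 3 for 18, 54 and 162 µg on day 1, 155, 147 and 2 on day 28, 39 and 2 for the difference between days at 18 and 162 µg, 137 and 1 for 162 against 18 µg on days 1 and 28, and 12 lists for 162 µg on day 1. On day 1 at 162 µg it reversed genes that had not been called: Itgax from 0.49 to −0.228, Ctsk from 0.44 to −0.086, Eln from −0.71 to 0.112, Cd79a from 0.64 to −0.06, Cd3d from 0.41 to −0.274, Clock from −0.38 to 0.077 and Per3 from 0.64 to −0.469. At 162 µg on day 28 Mt2 went from 1.24 to −0.029. The clock covariate gave 48, 27 and 64 for 18, 54 and 162 µg on day 1, 675 for 18 µg and 310 for 54 µg on day 28, and 5 lists for 162 µg on day 1. Arntl at 18 µg on day 28 went from −1.75 to 0.321 with it, by construction, since Arntl is part of the covariate. With an estimated correlation 0 lists were called for 162 µg on day 28.

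Leaving out 1 array gave 0 to 25 genes for 18 µg on day 1, with 25 without control replicate 1 and 5 without 18 µg replicate 2. For 54 µg on day 1 it gave 0 to 296: 296 without control replicate 1, 2 without any other control or 54 µg replicate 2, 1 without 54 µg replicate 5 and 0 without replicate 4. For 162 µg on day 1 it gave 9 to 251: without control replicates 1, 3, 4 and 5 it was 77, 14, 19 and 11, and without 162 µg replicates 1 to 5 in turn 11, 251, 9, 147 and 182. The lists of that comparison were 3 to 7, with 7 without 162 µg replicate 3 and 5 without 162 µg replicates 1 or 4 or control replicates 2 to 5. For 18 µg on day 28 it gave 22 to 52: 29, 30, 29 and 22 without control replicates 1, 3, 4 and 5, and 24 and 28 without 18 µg replicates 4 and 5. For 54 µg on day 28 it gave 0 to 6, with 3 without control replicate 2 and 0 without control replicates 1, 4 or 5 or any 54 µg replicate. For 162 µg on day 28 it gave 0 to 0, with 6 to 12 lists. The difference between days gave 0 to 5 at 18 µg (5 without day 1 replicate 5), 0 to 0 at 54 µg and 2 to 10 at 162 µg. The last was 10 without 162 µg day 1 replicate 5, 2 without 162 µg day 1 replicate 3, day 1 control replicate 5 or day 28 control replicate 1, and 3 without day 1 control replicate 4 or 162 µg day 28 replicates 1 or 4. For 162 against 18 µg it gave 9 to 23 on day 1 (23 without 18 µg replicate 5, 18 without 162 µg replicate 5) and 0 to 17 on day 28 (17 without 18 µg replicate 1, 1 without 162 µg replicate 3).

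Signal over background limits dim genes. The median Cy5 signal was 1.21 to 1.94 times its background, so folds of genes near background, such as Saa2 and Cxcl5 in controls, depend on the background correction and its offset.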

Other observations

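All genes and tests in this part were chosen after the results were seen. The genes called at 18 µg on day 28 held further clock outputs and regulators. Hlf, a factor of the Dbp family, rose by log2 1.20 (SE 0.20, adjusted p = 0.00162), Tef by 0.99 (SE 0.22, adjusted p = 0.0443) and Nr1d2 by 0.97 (SE 0.16, adjusted p = 0.00162). Cry2 rose by 0.70 and Bhlhe40 by 0.86 (adjusted p = 0.00192 and 0.0157). Zbtb16, a transcription factor induced by glucocorticoids, rose by 1.49 (SE 0.32, adjusted p = 0.0313). The index of Dbp minus Arntl had group means ± SD (n = 5) of 1.78 ± 2.06, 4.61 ± 0.32, 3.53 ± 0.35 and 2.86 ± 0.42 at 0, 18, 54 and 162 µg on day 1, and of −0.21 ± 1.28, 4.14 ± 1.01, 2.07 ± 0.56 and 1.01 ± 0.81 on day 28.

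Some genes called between all exposed and all control arrays, pooled over doses and days, are given as examples. No gene list was tested in this comparison. Lsm8, of the spliceosome, was lower by log2 0.65 (adjusted p = 9.66e-05), Isg15 by 0.78 (adjusted p = 0.000178), Bst2, an interferon-induced tether of viruses, by 1.05 (adjusted p = 0.000757) and H2-Q4, a class I antigen presentation gene, by 0.91 (adjusted p = 0.000203). Dhx37, an RNA helicase of ribosome assembly, was higher by 0.60 (adjusted p = 0.000312). With the clock index as a covariate these stood at −0.61, −0.58, −0.93, −1.10 and 0.56, each with an adjusted p of 0.0291 or less. On day 1 alone limma called 0 genes in this comparison and on day 28 alone 271, of which 240 were among the 1257 of both days.

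The 2 arrays that share a sample number correlated across genes at r = 0.978, against 0.775 to 0.978 for other pairs of that group. The 162 µg array with a day 1 title and day 28 characteristics had an acute phase mean of 0.72, against 0.59 to 1.49 for the other 162 µg arrays of day 28 and at least 1.73 for those of day 1.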
